A study of Mus musculus with 4 samples.

How the data were processed

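Polyadenylated RNA of purified pachytene spermatocytes was sequenced in 4 libraries, 2 of WT and 2 of Hsf5 knockdown mice, and the labels call the replicates biological. They do not say which animals were used, so p-values measure the spread between these libraries. The authors deposited one table of raw read counts per gene, with 1 column per library and 50763 genes, each row with a gene symbol. Per the submitters' processing notes, Trim Galore 0.6.10, HISAT2 2.2.1, featureCounts 1.5.3 and DESeq2 1.46.0 were used and the genome build was mm39. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here, so counts of gene families, of overlapping genes and of antisense partners are less certain. Every library's column was matched to its label by name.

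The depth was 33287428 to 42479164 counts per library. For a gene without a count in a group, a fold change was bounded with a floor of 3 counts over the group, 0.0339 CPM in the knockdown and 0.0481 CPM in WT. For 1 to 3 counts in the knockdown group the ratio has an exact 95% Poisson interval on that count. No interval was computed for genes with few counts in WT. Bounds and intervals cover counting error only.

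Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group left 23594 of the 36809 genes with a count, TMM factors scaled the libraries (0.854, 0.865, 1.11 and 1.22 for WT replicates 1 and 2 and knockdown replicates 1 and 2), and the quasi-likelihood F test compared knockdown with WT with Benjamini-Hochberg adjustment at 0.05 and no minimum fold. The biological coefficient of variation was 0.356. Standard errors are approximate, the log2 fold change divided by the square root of its F statistic. CPM values are TMM-scaled and computed from the deposited counts. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 25 lists. Camera asks whether a list differs from other genes. None of the list calls held with an estimated correlation, where 1 list had an unadjusted p below 0.05, and fry, which asks whether the genes of a list move on balance one way, gave 7. List medians were the same to 2 decimals when genes without a count in a group stood at their bounds. Differences between WT replicates within a list are medians of log2 CPM ratios with 0.5 CPM added.

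The groups, the tests, the 25 lists, all alternatives but one and the rule for named genes were set before the data were examined. The rule names Hsf5 and its family, the 10 largest rises and the 10 largest falls among genes past 0.05 with a mean of at least 5 CPM, with both knockdown values outside the WT range and no predicted or clone name, and per list up to 3 members past 0.05 with the smallest p, or 2 if none passed. Members that moved against their list or did not pass, where few, were named after their values were seen. Some genes that these rules select are not reported here. Of 803 list entries, 772 matched by symbol, 13 as mitochondrial names and 6 by synonym.

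Chromosomes came from RefSeq annotation of GRCm38, an older build than that of the counts, through gene symbols, with 46107 symbols (90.8%) matched. The table's order was used as a check: only 4 genes had a chromosome that differed from both neighbours. No coordinates are printed. Transcript lengths were those of the longest GENCODE M21 transcript per symbol, for 83.7% of tested genes.

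The test was checked on counts simulated from the WT means, the trend of dispersion on mean level and the real library sizes. There were 10 draws of 21816 tested genes with 200 changed. Of genes changed 2-fold 2.3% were called with the right sign, and of those changed 4-fold 51.3%, and 6.47% of calls were false. With so few changed genes the adjusted threshold is stricter than in the real comparison, so these shares do not carry over to it. Of 50 simulated lists shifted 2-fold 50 were called, and of 50 unshifted lists 1 was called down. Genes were simulated independently and the lists drawn at random. The list check therefore does not cover lists of genes that vary together.

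Alternatives were DESeq2 size factors in the same edgeR fit, library totals only, no filter, a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, the replicate number as a block, leaving out each library, a log2 fold change of at least 1, and glmTreat against 1.5-fold. Scaling on the synaptonemal complex and cohesin genes was added after seeing the data.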

Results

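Gene expression was measured by sequencing polyadenylated RNA of pachytene spermatocytes purified from mouse testis. Pachytene is the long stage of the first meiotic prophase in which homologous chromosomes are fully paired and the X and Y are transcriptionally silenced. There were 2 libraries from wild-type (WT) mice and 2 from mice with a knockdown of Hsf5, a testis member of the heat shock factor family of transcription factors. The counts assigned to genes summed to 39331933 and 33287428 in WT replicates 1 and 2, and to 42479164 and 33947608 in knockdown replicates 1 and 2. Replicates were much closer to each other than to the other group: across genes, Pearson's r of log2 CPM (read counts scaled to library size) was 0.962 within WT, 0.976 within the knockdown and 0.602 to 0.705 between the groups, with the caution that genes are not independent replicates. The counts of neither pair agreed within sampling noise (chi-square per degree of freedom 63.7 in WT and 138 in the knockdown), and each library was counted as 1 replicate.

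The comparison asks how the expression of pachytene cells changes when Hsf5 is knocked down. The targeted gene itself was read first. Hsf5 stood at 586 and 449 CPM in the WT libraries and at 287 and 238 CPM in the knockdown libraries, a log2 fold change of -0.98 with a standard error of 0.31 (edgeR quasi-likelihood test, adjusted p = 0.0217, n = 2 per group). Both knockdown libraries lay below both WT libraries, and neither was near 0. With library totals as the only scaling the log2 fold change was -0.55 and did not pass the test (edgeR, adjusted p = 0.115), and it did not pass without WT replicate 1 (-0.79, adjusted p = 0.219) or without WT replicate 2 (-1.13, adjusted p = 0.0725). Among the other members of the family, Hsf2, a factor with a known role in spermatogenesis, rose by 1.36 (SE 0.33) on the log2 scale, a call lost without WT replicate 2 (edgeR, adjusted p = 0.0702). Hsfy2 had 31.2 and 16.4 CPM in WT and no count in the knockdown libraries, which is at least 719-fold lower. Hsf4 was near the floor in WT, at 0.0298 and 0.0695 CPM, against 0.699 and 0.582 CPM in the knockdown. Its rise did not pass without WT replicate 1 (edgeR, adjusted p = 0.107), knockdown replicate 1 (0.0896) or knockdown replicate 2 (0.0535). Hsf1 (log2 fold change 0.25, SE 0.29) and Hsf2bp, a partner of Hsf2 with a role in meiotic recombination (-0.72, SE 0.35), did not pass. Hsf2bp did pass as lower without knockdown replicate 1 (-1.21; edgeR, adjusted p = 0.0136) and when scaled on synaptonemal complex and cohesin genes (-1.13, adjusted p = 0.017). As a list, the 6 measured HSF family genes held 2 that rose, 2 that fell and 2 that did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.78).

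Across the transcriptome, 6467 of the 23594 genes tested were higher in the knockdown libraries and 7902 were lower. Of these, 2460 were higher and 4615 lower by 8-fold or more on the fitted scale. No count was found in either knockdown library for 1358 of the lower genes, whereas 168 of the higher genes had no count in either WT library. The median log2 fold change of all genes was -0.12. It was 0.31 with library totals as the only scaling and -0.44 when the libraries were scaled on synaptonemal complex and cohesin genes, a scaling chosen after the data were seen, under which 4411 genes were higher and 8220 lower. The fold changes of the groups described next are not centred on that median and shift with the scaling. A change given with an SE is on the log2 scale.

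**Figure D1:**
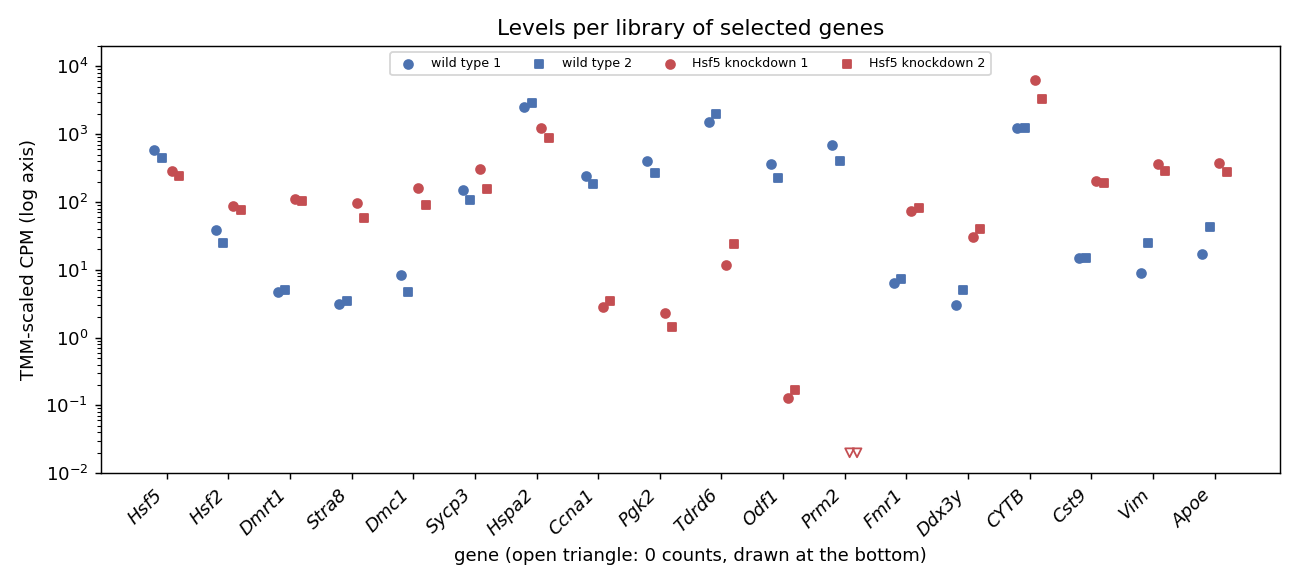
TMM-scaled CPM (vertical log axis) of 18 genes (horizontal axis) in each of the 4 libraries, with WT in blue and Hsf5 knockdown in red, circles for replicate 1 and squares for replicate 2, and open triangles for 0 counts. Hsf5 lies at 586 and 449 CPM in WT and at 287 and 238 CPM in the knockdown, while Prm2 has no count in either knockdown library.

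The 10 largest fitted falls under the naming rule were of genes without a count in the knockdown libraries, among them genes of sperm formation. Their order followed their WT level, and only bounds on their falls can be given. Prm2, one of the protamines that pack sperm DNA, had 687 and 401 CPM in WT and no count in the knockdown, at least 16359-fold lower. Smcp, a protein of the sperm mitochondrial capsule, was at least 11838-fold lower and Tcp10c at least 11505-fold lower. Toporsl, Prr30, Allc, Speer2, Tmco5 and Cylc2, the last a cytoskeletal protein of the sperm head, also had no count in the knockdown libraries, and their bounds ran from at least 2293-fold to at least 5198-fold lower. Speer2 and Tcp10c belong to families of similar copies, so their counts are less certain.

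All 36 measured genes of the round and elongating spermatid list fell, 36 also adjusted over the list alone, with a median log2 fold change of -8.08 (camera, adjusted p = 1.2e-31, and adjusted p = 0.47 with an estimated correlation). Odf1, of the outer dense fibres of the sperm tail, went from 357 and 225 CPM to 0.127 and 0.17 CPM, and Akap4, of the fibrous sheath, fell by 11.97 (SE 0.57) on the log2 scale. The cilium and flagellum list had 42 of 48 genes lower and none higher (43 lower adjusted over the list alone), with a median of -3.80 (camera, adjusted p = 3.7e-21, and adjusted p = 0.179 with an estimated correlation). Qrich2 went from 1386 and 1956 CPM to 0.572 and 0.679 CPM, and the axonemal dynein genes Dnai2 and Dnah17 fell, with log2 fold changes of -7.07 (SE 0.41) and -8.43 (SE 0.51). Between the WT libraries the spermatid list also differed, with a median log2 ratio of replicate 2 to replicate 1 of -0.81, whereas that of the cilium and flagellum list was 0.05.

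Genes that normally come on in mid and late pachytene fell together. Of the 33 measured, 29 fell, 1 (Cpeb1) rose and 3 (H1f6, Brdt and Kdm3a) did not pass, and adjusted over the list alone 30 fell and 1 rose. The median was -2.29 (camera, adjusted p = 5.4e-12, and adjusted p = 0.47 with an estimated correlation). Ovol2, a zinc finger transcription factor, went from 223 and 164 CPM to 1.88 and 1.87 CPM. Adam3, a sperm surface protein needed for fertilisation, and Pgk2, the testis phosphoglycerate kinase, had log2 fold changes of -6.91 (SE 0.41) and -7.50 (SE 0.45). Metabolic enzymes of the germ line moved likewise, with 21 of 26 lower (22 adjusted over the list alone), Glud1 and Acsbg1 higher and a median of -4.42 (camera, adjusted p = 5.4e-12, and adjusted p = 0.47 with an estimated correlation). Acsbg2 (log2 fold change -9.46, SE 0.52), the sperm sodium pump gene Atp1a4 (-9.23, SE 0.53) and Pgam2 (-7.07, SE 0.40) fell. In the list of meiotic division and G2/M genes 16 of 32 fell, 4 (Bub1, Mad2l1, Ccna2 and Cdc25b) rose and 12 did not pass, with the same counts adjusted over the list alone, and the list as a whole did not stand apart from other genes (median -0.84, and -0.41 with library totals only; camera, adjusted p = 0.212). The largest fall there was that of Ccna1, the germ cell cyclin A needed to leave meiotic prophase, from 242 and 186 CPM to 2.82 and 3.44 CPM, and Aurkc and Fbxo43, both regulators of meiotic division, had log2 fold changes of -4.36 (SE 0.47) and -2.09 (SE 0.30).

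**Figure D2:**
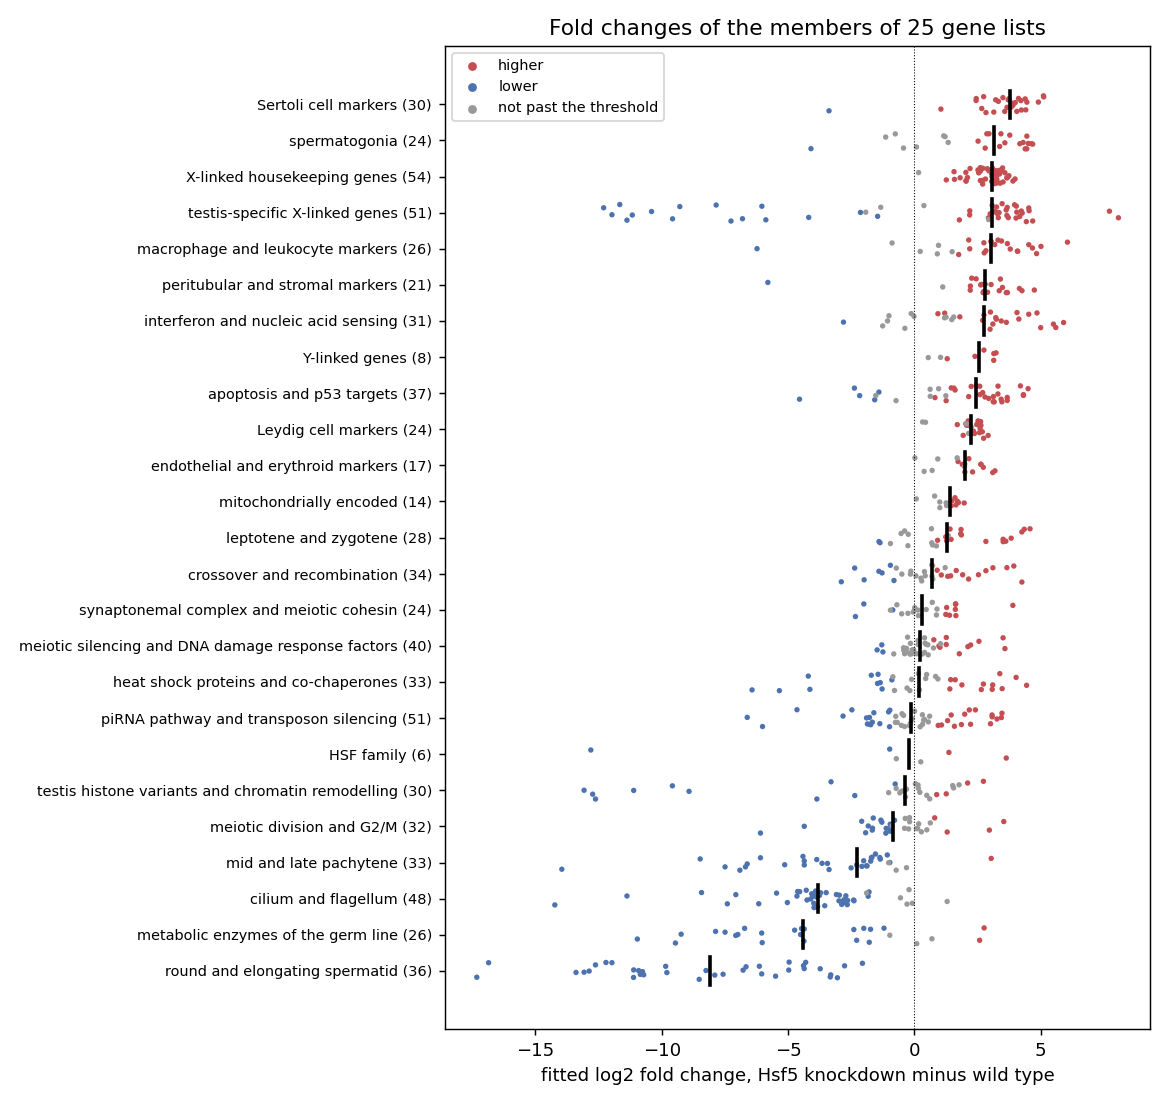
Fitted log2 fold change (horizontal axis, knockdown minus WT) of each measured member of the 25 gene lists (vertical axis, number of members in brackets), red for higher, blue for lower and grey for not past the threshold, with a black bar at each list's median. Medians run from -8.08 for round and elongating spermatid genes to 3.78 for Sertoli cell markers, and fitted values of genes without a count in 1 group depend on the prior count.

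Genes of earlier germ cells rose. In the spermatogonia list 16 of 24 genes rose and 1 fell, also adjusted over the list alone, with a median of 3.16 (camera, adjusted p = 8.9e-06, and adjusted p = 0.47 with an estimated correlation). Sertoli cell markers, given below with the other somatic cells, rose with them, with a median of 3.78. Dmrt1, a regulator that holds spermatogonia out of meiosis and is also expressed in Sertoli cells, went from 4.71 and 5.07 CPM to 111 and 103 CPM, and Sohlh2, a factor of spermatogonial differentiation, rose by 4.38 (SE 0.35) on the log2 scale. Dmrtb1, which acts at the turn from mitosis to meiosis, was the exception and fell from 1164 and 1004 CPM to 70.5 and 56.2 CPM. In the leptotene and zygotene list 16 of 28 rose and 2 (Spo11 and Iho1) fell, and 17 rose and 3 fell adjusted over the list alone, with a median of 1.30 (camera, adjusted p = 0.0002, and adjusted p = 0.573 with an estimated correlation). Stra8 and Meiosin, which start the meiotic programme, rose by 4.57 (SE 0.41) and 3.62 (SE 0.36) on the log2 scale. The X-linked gene Scml2, of a Polycomb protein of the germ line, rose by 3.51 (SE 0.34), and X-linked genes had a median of 2.89.

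The machinery that pairs and recombines chromosomes moved in both directions. In the list of synaptonemal complex and meiotic cohesin genes 8 of 24 rose, 3 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.31, and -0.06 when scaled on these genes; camera, adjusted p = 0.2). Without knockdown replicate 2 the list passed upward (median 0.60; camera, adjusted p = 0.0179), and its median was 0.07 without knockdown replicate 1 and 0.74 with library totals only. The cohesin subunit gene Rad21l rose by 3.89 (SE 0.62) on the log2 scale, whereas Terb1, of the complex that ties telomeres to the nuclear envelope, fell from 87.8 and 80.3 CPM to 22.02 and 19.9 CPM and Syce1, of the central element, had a log2 fold change of -2.34 (SE 0.37). Of 34 crossover and recombination genes 13 rose, 7 fell and 14 did not pass (12 and 7 adjusted over the list alone), with a median of 0.69 (camera, adjusted p = 0.0419, and adjusted p = 0.649 with an estimated correlation). Without WT replicate 1 the list's call was lost (camera, adjusted p = 0.0915), as it was with a mean of at least 1 CPM required (0.0885). It was also lost without knockdown replicate 1 (median 0.38, adjusted p = 0.0952) and when scaled on the synaptonemal complex and cohesin genes (median 0.31, adjusted p = 0.0518), whereas with library totals only it passed with a median of 1.12. Dmc1, the meiotic recombinase, and Tex11, an X-linked crossover factor, rose by 4.25 (SE 0.45) and 3.66 (SE 0.40), and Prr19, needed for crossover formation, fell by 2.90 (SE 0.33) on the log2 scale. Among 40 meiotic silencing and DNA damage response factors 11 rose, 3 (Rnf168, Dot1l and Pias4) fell and 26 did not pass, or 6 and 3 adjusted over the list alone (median 0.23, and -0.09 when scaled on synaptonemal complex and cohesin genes; camera, adjusted p = 0.0802). This list passed upward with library totals only (median 0.66; camera, adjusted p = 0.031), without the low-count filter (0.27, adjusted p = 0.0432) and without knockdown replicate 2 (0.34, adjusted p = 0.0448). Its median was 0.08 without knockdown replicate 1 (adjusted p = 0.112) and 0.09 with a mean of at least 1 CPM required (adjusted p = 0.177). Kdm6a, an X-linked histone demethylase, rose by 3.58 (SE 0.52) and the kinase gene Atm by 2.55 (SE 0.44).

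The list of piRNA pathway and transposon silencing genes was divided. It holds genes of the piRNA pathway, which silences transposons in the germ line, together with others such as Dnmt1, Setdb1 and Rnaseh2a. The split is that of the mixed list. Of 51 genes 16 rose, 16 fell and 19 did not pass (16 and 17 adjusted over the list alone). The median was -0.12 and the mean -0.09, and the median was 0.31 with library totals only, -0.48 when scaled on synaptonemal complex and cohesin genes, and between -0.22 and 0.04 without 1 of the libraries. The list test pointed up without passing (camera, adjusted p = 0.622). Tdrd6, a Tudor protein of the chromatoid body, went from 1502 and 1982 CPM to 11.6 and 23.8 CPM, and Rnaseh2a, a subunit of the enzyme that cuts RNA in RNA-DNA hybrids, fell by 4.65 (SE 0.36) on the log2 scale. The DNA methyltransferase gene Dnmt3a rose by 3.46 (SE 0.37). Transposon transcripts were not analysed here. Heat shock proteins and co-chaperones were divided too, with 12 of 33 higher, 10 lower and 11 not past the test, the same counts adjusted over the list alone (median 0.20, and -0.19 when scaled on synaptonemal complex and cohesin genes; camera, adjusted p = 0.351). The median of the heat shock list was -0.16 without knockdown replicate 1, 0.53 without knockdown replicate 2, 0.07 without WT replicate 2, 0.37 without WT replicate 1 and 0.62 with library totals only. Hspb1, a small heat shock protein, went from 4.05 and 4.03 CPM to 92.5 and 82.8 CPM, whereas the testis chaperone gene Hspa1l and Dnajb13, whose product sits in sperm flagella, had log2 fold changes of -5.35 (SE 0.42) and -4.20 (SE 0.33). Hspa1l has close copies, so its counts are less certain.

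Chromatin proteins included the transition proteins and other spermatid proteins that fell deeply. Of 30 testis histone variants and chromatin remodelling genes 10 fell, 4 rose and 16 did not pass, or 9 and 4 adjusted over the list alone (median -0.39, and 0.03 with library totals only; camera, adjusted p = 0.0532). The list passed downward without knockdown replicate 1 (median -0.71; camera, adjusted p = 0.00715) and when scaled on synaptonemal complex and cohesin genes (-0.76, adjusted p = 0.0471), and its median was -0.15 without WT replicate 1 and -0.10 without knockdown replicate 2. The transition protein genes Tnp1 and Tnp2, which replace histones in spermatids, went from 371 and 143 CPM to 0.127 and 0.097 CPM and from 747 and 289 CPM to 0.0424 and 0.0727 CPM. H1f7, a spermatid linker histone, had 1 count in the knockdown group against 5864 in WT, a ratio of 8326 with a 95% counting interval from 1494 to 328840.

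The X chromosome had the highest median fold change of the chromosomes. Its 817 tested genes had a median log2 fold change of 2.89, against -0.15 for the 21520 autosomal genes, a difference of 3.04 (camera over chromosomes, adjusted p = 5.8e-12, and adjusted p = 0.904 with an estimated correlation). On X 555 genes rose and 135 fell. Among genes with a mean of 10 CPM or more over the 4 libraries, 92.8% of 222 X-linked genes rose, compared with 30.4% of 10127 autosomal genes. Between 1 and 10 CPM 66.9% of 372 X-linked genes rose and 19.4% fell, and below 1 CPM 44.8% of 223 rose and 25.6% fell, while 28% and 16.2% of the autosomal genes at those levels rose. These levels include the knockdown libraries, so X-linked genes that rose lie in higher classes than their WT level alone would give. X-linked genes took 0.246% and 0.265% of all counts in the WT libraries and 1.45% and 2.01% in the knockdown libraries. X-linked housekeeping genes rose almost without exception, 53 of 54 with only Phf6 not past the test (53 adjusted over the list alone), and their median was 3.08 (camera, adjusted p = 8.9e-15, and adjusted p = 0.47 with an estimated correlation). Fmr1 went from 6.38 and 7.33 CPM to 73.5 and 80.3 CPM, and Taf1 and Hprt1 rose by 3.98 (SE 0.41) and 3.90 (SE 0.44) on the log2 scale. These genes also differed between the WT libraries, with a median log2 ratio of replicate 2 to replicate 1 of 0.88.

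**Figure D3:**
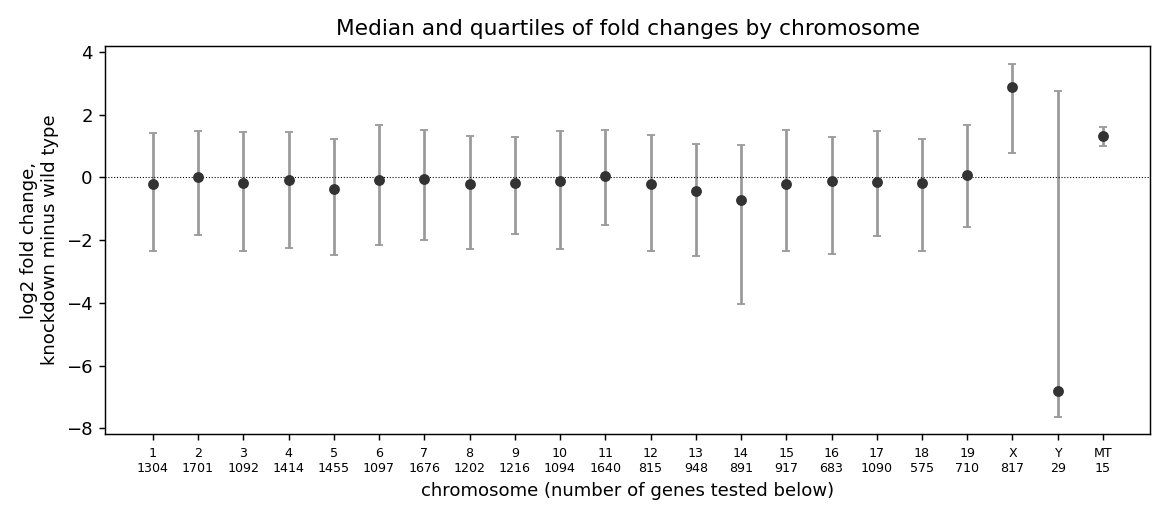
Median log2 fold change (vertical axis, knockdown minus WT) of the genes tested on each chromosome (horizontal axis, number of genes below each name), with bars from the lower to the upper quartile of genes. The X median is 2.89 with 817 genes, the mitochondrial median 1.32 with 15, and the Y median -6.81 with 29.

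Testis-specific X-linked genes split. Of 51 measured, 31 rose, 16 fell and 4 did not pass (32 and 17 adjusted over the list alone). For 9 of the 51 a group had no count, so their fitted values, and with them the list's mean, depend on the prior count. The median was 3.07, but the mean was -0.21, and the list test pointed up (camera, adjusted p = 0.0419, and adjusted p = 0.649 with an estimated correlation), a call lost without WT replicate 2 (camera, adjusted p = 0.0724) and without knockdown replicate 1 (0.0735), with library totals only (0.0682) and with a mean of at least 1 CPM required (0.141). The members with the smallest p were ones that fell: Akap4, given with the spermatid genes, Tsga8 (log2 fold change -4.19, SE 0.40) and Cypt1 (-7.26, SE 0.72, with close copies on X). Among Y-linked genes 6 of 8 rose, also adjusted over the list alone, and Zfy1 and Zfy2 did not pass. The median was 2.57 (camera, adjusted p = 0.00686, and adjusted p = 0.573 with an estimated correlation), and 1.34 without the low-count filter. Uba1y, Ddx3y and Usp9y rose by 3.14 (SE 0.41), 3.14 (SE 0.44) and 2.39 (SE 0.45) on the log2 scale. Over the whole Y chromosome, where many genes are near-identical copies with uncertain counts, 10 of 29 genes rose and 17 fell.

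Genes of cell death and of innate immune signalling rose. Of 37 apoptosis and p53 target genes 26 rose, 5 (Fasl, Zmat3, Bak1, Ddit3 and Bcl2l1) fell and 6 did not pass, or 28 and 6 adjusted over the list alone. The median was 2.44 (camera, adjusted p = 2.3e-05, and adjusted p = 0.47 with an estimated correlation). Gadd45b rose by 4.19 (SE 0.41), the cell cycle inhibitor gene Cdkn1a by 3.67 (SE 0.44) and Phlda3 by 4.31 (SE 0.56) on the log2 scale. Of 31 interferon and nucleic acid sensing genes 20 rose, Cgas fell and 10 did not pass, with the same counts adjusted over the list alone. The median was 2.75 (camera, adjusted p = 8.8e-05, and adjusted p = 0.47 with an estimated correlation). Cxcl10, an interferon-induced chemokine, went from 2.89 and 4.62 CPM to 115 and 57.9 CPM, and the transcription factor gene Irf9 rose by 3.64 (SE 0.47).

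The 10 genes with the largest rises included the interferon regulatory factor gene Irf1 (1.76 and 5.39 CPM in WT, 237 and 107 CPM in the knockdown), the NF-kB inhibitor gene Tnfaip3 (1.16 and 1.67 CPM, then 126 and 69.5 CPM) and the stress-induced transcription factor gene Atf3 (1.01 and 2.09 CPM, then 95.1 and 41.4 CPM). Edn1, the precursor of a vasoconstrictor peptide, rose by 6.28 (SE 0.51), Igfbp3 by 6.11 (SE 0.47), the cytokine receptor gene Tnfrsf12a by 6.39 (SE 0.72), and Pcsk1n, Plppr4 and Ildr2 by 5.50 (SE 0.36), 5.55 (SE 0.72) and 5.41 (SE 0.69) on the log2 scale. The linker histone gene H1f1 ranked first, but 1 library decided it: knockdown replicate 1 had 23.4 CPM and replicate 2 had 0.582 CPM, and without replicate 1 the log2 fold change was 2.64 and did not pass (edgeR, adjusted p = 0.158).

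Markers of the somatic cells of the testis were higher in the knockdown libraries, beside the spermatogonial, X-linked, immune and cell death genes above. Of 30 Sertoli cell markers 29 rose and Fabp9, which male germ cells express, fell, also adjusted over the list alone. The median was 3.78 (camera, adjusted p = 4.7e-14, and adjusted p = 0.47 with an estimated correlation). Cst9 went from 15.1 and 15.1 CPM to 201 and 193 CPM, and Cst12 and Cldn11, a tight junction protein of the blood-testis barrier, rose by 4.21 (SE 0.36) and 4.23 (SE 0.41) on the log2 scale. Of 24 Leydig cell markers 19 rose, none fell and 5 did not pass, or 21 rose adjusted over the list alone. The median was 2.24 (camera, adjusted p = 7.5e-05, and adjusted p = 0.603 with an estimated correlation), 1.465 without WT replicate 1 and 4.26 without WT replicate 2. Gstm2, Scarb1 and Ptgds rose by 2.92 (SE 0.55), 1.69 (SE 0.33) and 2.57 (SE 0.50). The Leydig list also differed between the WT libraries, with a median log2 ratio of replicate 2 to replicate 1 of 2.63, and the Sertoli list did so with 0.96. Of 21 peritubular and stromal markers 19 rose, Actg2 fell and Cnn1 did not pass, with the same counts adjusted over the list alone. The median was 2.80 (camera, adjusted p = 1.9e-05, and adjusted p = 0.573 with an estimated correlation). Vim went from 8.85 and 24.9 CPM to 363 and 282 CPM, and Fn1 and Myl9 rose by 3.40 (SE 0.41) and 4.15 (SE 0.51). Of 26 macrophage and leukocyte markers 20 rose, Aif1 fell (-6.23, SE 0.79) and 5 did not pass, or 20 and 2 adjusted over the list alone. The median was 3.03 (camera, adjusted p = 6.6e-05, and adjusted p = 0.577 with an estimated correlation). Apoe rose by 3.45 (SE 0.46) and Fcer1g by 4.83 (SE 0.73). Of 17 endothelial and erythroid markers 11 rose and 6 did not pass, or 12 rose adjusted over the list alone. The median was 1.99 (camera, adjusted p = 0.00688, and adjusted p = 0.577 with an estimated correlation). Egfl7 rose by 2.63 (SE 0.57), the X-linked gene Alas2 by 2.15 (SE 0.50) and Hbb-bs by 3.19 (SE 0.82). Levels in WT were low: 6 of the 17 had a mean of at least 1 CPM there, and Hbb-bs stood at 0.149 and 0.556 CPM.

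Mitochondrially encoded transcripts took 0.684% and 0.755% of the counts in the WT libraries and 3.56% and 2.47% in the knockdown libraries. Of 14 measured, 8 rose, none fell and 6 did not pass, or 9 rose adjusted over the list alone. The median was 1.39 (camera, adjusted p = 0.0067, and adjusted p = 0.577 with an estimated correlation). CYTB, of respiratory complex III, went from 1249 and 1215 CPM to 6303 and 3336 CPM, COX3 rose by 1.74 (SE 0.38) and ND5 by 1.60 (SE 0.39) on the log2 scale, the last not past the test without WT replicate 1 (edgeR, adjusted p = 0.0934). Across 16021 genes with a transcript length, longer transcripts had higher fold changes (Spearman's rho 0.21 across genes, which are not independent replicates), and the same trend separated replicate 2 from replicate 1 in WT (0.35) and in the knockdown (0.42).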

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

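Of the alternatives, only the scaling on synaptonemal complex and cohesin genes was chosen after seeing the data. Genes higher in the knockdown numbered 4411 to 8121 and genes lower 6051 to 8736 over all alternatives, within 1.5 times the reported counts, and no gene called under both the reported and another fit changed sign. Hsf5 was lower under every alternative run, but its log2 fold change was -0.55 with library totals only (adjusted p = 0.115) and -1.13 to -0.79 without 1 library, not past the threshold without either WT replicate. Its adjusted p ran from 0.00203 to 0.219. The cause was not tested for the totals, while leaving out a library leaves fewer samples, and the lone library of a group is then assumed to vary like the other group. The X minus autosomal difference was 2.55 to 3.40 throughout and lost its call at 3.04 with an estimated inter-gene correlation (adjusted p = 0.904). Of 25 lists 18 passed with camera, 0 with an estimated correlation and 7 with fry, with 16 to 20 under other alternatives. The estimated correlations themselves widen the test. Named genes other than Hsf5 gave 1022 single comparisons with an alternative. Of these 1013 kept their side of the threshold, 6 lost it and 3 gained it. Of 300 comparisons for single lists 255 kept it, 38 lost it and 7 gained it. The samples share only a replicate number: with it as a block 15367 genes passed against 14369, the X difference was 3.15 and Hsf5 -0.97. Under the block the testis-specific X-linked list did not pass (camera, adjusted p = 0.104), the testis histone list passed downward (0.00982) and Hsf2bp passed as lower (edgeR, adjusted p = 0.0117), and the replicate 1 minus 2 differences of both groups correlated with r = 0.297 across 18053 genes. Depth limits genes without a count in a group to bounds.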

Other observations

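All tests in this part were chosen after the results were seen. A set of 31 immediate-early and NF-kB genes, also put together after their values were seen, was measured in full, and 28 were higher in the knockdown libraries and none was lower. Egr1 went from 27.8 and 86.8 CPM in WT to 660 and 808 CPM in the knockdown, Fosb from 23.4 and 71.1 CPM to 785 and 729 CPM, Junb from 14.5 and 50.5 CPM to 539 and 476 CPM, and Nfkbia from 2.18 and 5.25 CPM to 200 and 115 CPM. Klf4, Fosl1 and Ier5 did not pass. Markers of Sertoli, peritubular and stromal, and macrophage and leukocyte cells rose as well, with medians of 3.78, 2.80 and 3.03 on the log2 scale. The Sertoli and the peritubular and stromal lists were also higher in WT replicate 2 than in WT replicate 1 (median log2 ratios 0.96 and 1.11). For the macrophage and leukocyte list that ratio was 0.14. Between the knockdown libraries the lists did not move together. There the median log2 ratio of replicate 2 to replicate 1 was 0.23 for Sertoli, -0.73 for peritubular and stromal, and -1.12 for macrophage and leukocyte markers.

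Replication-dependent histone genes, 27 of them tested, showed no shared direction, with 9 higher and 8 lower in the knockdown and 19 higher in knockdown replicate 1 than in replicate 2.

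X-linked genes were higher in the knockdown libraries, and RNA of other cells was weighed as the source. Outside the Rhox and Xlr families and Tsx, 23 of 42 testis-specific X-linked genes rose and 16 fell. This subset was set after the values were seen. The count cannot decide on RNA of somatic cells as the whole cause, because expression of these genes in somatic cells was not tested. For housekeeping genes that source stays open too. The median of 30 Sertoli markers, 29 with at least 1 CPM in WT and 1 in another list too, exceeded theirs by 0.7035 (bootstrap SE 0.172). Both sets were higher in WT replicate 2. The abundant Sertoli gene Clu stood at 110 and 301 CPM in WT and 2506 and 3007 CPM in the knockdown despite purification. More germ cells from before pachytene, in which X is active, are also a candidate, with 66.7% of spermatogonia genes and 57.14% of leptotene and zygotene genes higher. Loss of silencing within pachytene cells of the knockdown stays open and untested, because bulk counts do not separate cells.

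Late-stage germ cell genes were lower in the knockdown libraries, and RNA of haploid cells in the WT libraries is a candidate source. For the spermatid list it stays open and was not tested, though the list differed between the WT libraries (median log2 ratio of replicate 2 to 1 of -0.59 with the length trend removed). If it were the whole cause for mid and late pachytene genes, the log2 ratio of WT replicate 2 to 1 would follow that of the spermatid list and lie near -0.52, and it lay above the implied values by 0.4013 (95% bootstrap interval 0.302 to 0.546). For cilium and flagellum genes the gap was 0.5344 (0.418 to 0.601). The intervals cover the spread over genes and not that between libraries, and both gaps rest on a single pair of libraries and an assumed mixture. For these genes haploid RNA therefore cannot be told apart from an arrest of the knockdown cells before late pachytene, which was not tested.

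Hsf5 was lower by about 2-fold in the knockdown libraries. Fewer cells of the stages that hold Hsf5 RNA may account for it, and 29 of the 33 mid and late pachytene genes had a lower fold change than Hsf5. That count cannot decide it, because a knockdown of the transcript with deeper falls of these genes would give the same. A knockdown of the transcript itself stays open and was not tested, since gene-level counts do not show which part of the transcript remained.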
